A study of Mus musculus with 6 samples.

How the data were processed

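RNA was sequenced from dissected mouse kidneys at E15.5 (embryonic day). The 6 libraries fall into 2 groups of 3, assigned from the titles and genotype labels. Kidneys with a Foxd1-driven Cre recombinase and floxed Yap1 and Wwtr1 alleles (called knockout kidneys here, since Cre acts in the Foxd1 lineage of the stroma) were compared with wild-type kidneys. Per the labels, the strain was mixed, kidneys were kept in an RNA-stabilising solution, RNA was extracted with a column kit for small samples, and libraries followed a standard Illumina preparation. Whether the library kit kept strand information, and whether the 3 libraries of a group came from separate embryos or litters, is not given in the sources used here. P-values therefore measure the spread between these libraries, which may be partly technical.

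Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and quantified with Salmon, with the genome build GRCm38 (mm10). The version of Salmon, the annotation release, the summing of transcripts to genes and any filter are not given in the sources used here. The authors deposited FPKM values, fragments per kilobase of transcript scaled to library size, for 24749 Ensembl gene identifiers in 1 table, and all of its columns were used. In every library the median log2 ratio to the gene-wise geometric mean was 0.0038, so the deposited values already carried a median-of-ratios scaling between libraries. A symbol was found for 24469 identifiers. Gene positions and overlaps were taken from GENCODE M21 on GRCm38, the build named in the processing notes. No pair among the 15 pairs of libraries held identical values.

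The table holds no counts. Depth was approximated from its low end, because on a gene with 1 annotated transcript of at least 2 kb the lowest values fell on clear steps, of which the lowest stands for 1 fragment. This gave between 12700000 and 15500000 fragments per library on the authors' scaled values, and 1 fragment on a 2 kb transcript was worth 0.0323 to 0.0393 FPKM. The length minimum, the range searched and the step rule for short gene models were set after looking at the values. The estimate is approximate, since it takes the full annotated length as the length used for quantification.

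FPKM values are not counts, so no count model was fitted. Genes with a mean of at least 0.5 FPKM over the 6 libraries were kept, which left 16899. Values were transformed as log2(FPKM + 1), with a pseudocount of 1, and limma 3.58.1 in R 4.3.3 was fitted with genotype as the only term and empirical Bayes moderation with trend and robust options. Log2 changes are on this scale, knockout minus wild type, which understates the change of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For Yap1 and Wwtr1 an exact two-sided permutation test over the 20 assignments was added, whose smallest p is 0.1. Fold changes and percentages of wild type are ratios of mean FPKM.

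The comparison, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The 32 lists cover targets of YAP and TAZ, Hippo pathway components, cell types of the embryonic kidney (cortical and medullary stroma, pericytes, smooth muscle, renin and mesangial cells, nephron progenitors, early nephrons, podocytes, proximal tubule, loop and distal tubule, ureteric tip, collecting duct with urothelium, endothelium, macrophages), extracellular matrix, red blood cells, cell cycle, hypoxia, immediate early genes, p53 targets, interferon response, neighbouring tissues (adrenal cortex, nerve and chromaffin cells, glia, skeletal muscle, cartilage, gonad, liver), sex-linked genes and mitochondrial transcripts. Of 368 list genes, 364 were in the table and 329 were tested. The 31 lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists. Member calls are given over all genes tested and adjusted over the list alone.

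Named genes are Yap1 and Wwtr1. To these were added the 8 called genes with the largest increase and the 8 with the largest decrease. These had to reach a mean of at least 1 FPKM in a genotype, show no overlap between genotypes and carry a proper symbol. From each list up to 4 called members with the smallest p were named, or the 2 members with the smallest p where fewer than 2 were called. Further members of the control lists (red blood cells, neighbouring tissues, mitochondrial transcripts, sex-linked genes) could be named where they moved with the genotype. Some genes that the rule names are not reported here. Other genes are said to be chosen after their values were seen.

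The procedure was tested on 10 simulated tables of the 16899 genes with 200 changed genes each. It recovered 70.9% of genes changed by a log2 of 0.5, 96.2% of those changed by 1 and 99.4% of those changed by 2, and 5.29% of its calls were false. A list shifted by -0.3 was called in 10 of 10 tables, and 0 of 300 unshifted lists were called. Genes were simulated independently of each other and without a deviating library. These tables therefore cannot show how often lists of correlated genes, or genes in a deviating library, are called falsely.

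Alternatives covered the pseudocount (0.1), the filter (none beyond a value above 0 in a library, or a mean of at least 5 FPKM) and the scaling (equal sums per library, size factors, quantile normalization, equal sums without globin and mitochondrial genes). They also covered a replicate term, moderation without the robust option, stricter thresholds, and each library left out in turn. Leaving out gene models of short RNAs was added after the data had been seen. An alternative planned for count tables was not run, because the values are FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.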

Results

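YAP and TAZ, encoded by Yap1 and Wwtr1, are transcriptional co-activators at the end of the Hippo pathway. Foxd1 marks the stromal progenitors of the embryonic kidney, from which interstitial fibroblasts, pericytes, vascular smooth muscle, mesangial cells and renin cells arise. The series asks how loss of both co-activators from this lineage bears on pericyte differentiation. RNA from whole dissected kidneys was profiled at E15.5 (embryonic day) in 3 knockout libraries (Foxd1-driven Cre with floxed Yap1 and Wwtr1) and 3 wild-type libraries. All cell types of the organ therefore contribute to each value. Depth was approximated at 12700000 to 15500000 fragments per library, and between 19704 and 20013 genes had a value above 0.

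The floxed genes were examined first. Wwtr1 (chromosome 3, 57455649 to 57575910, GRCm38) fell from 18.8 ± 1.26 FPKM (SD, n = 3) in wild-type kidneys to 12.9 ± 0.635 FPKM (SD, n = 3) in knockout kidneys, which is 68.4% of wild type. Its log2 change was -0.51 (SE 0.07, limma adjusted p = 0.0235), and all 3 knockout libraries lay below all 3 wild-type libraries (exact permutation p = 0.1, the smallest that 3 against 3 allows). Yap1 (chromosome 9, 7931999 to 8004596) measured 51.0 ± 4.95 FPKM in wild-type and 45.4 ± 2.94 FPKM in knockout kidneys (SD, n = 3 each). That log2 change of -0.16, with a 95% confidence interval from -0.36 to 0.03, did not pass the test (adjusted p = 0.378, exact permutation p = 0.2). These are levels of the whole gene, and which exons are floxed is not given in the sources used here, so transcripts lacking those exons are counted too. Yap1 shares exon sequence with the gene model Gm20416 on the opposite strand. The Wwtr1 call was lost when libraries were rescaled to equal sums (log2 -0.53, adjusted p = 0.0516), with or without globin and mitochondrial genes. It was also lost without wild-type library 2 or knockout library 1, 2 or 3 (log2 between -0.55 and -0.48, adjusted p = 0.0701, 0.0682, 0.115 and 0.117). Over all alternatives its adjusted p lay between 0.0111 and 0.117. Foxd1 itself measured 7.64 ± 1.31 FPKM in wild-type and 4.50 ± 0.617 FPKM in knockout kidneys (SD, n = 3 each), and its log2 change of -0.65 was not called (adjusted p = 0.0886). Whether the Cre allele replaces coding sequence of Foxd1 is not given in the sources used here, so this value does not separate the allele from a change in the cells that express Foxd1.

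Across the transcriptome most called genes were lower in knockout kidneys. Of 16899 genes tested, 124 were called by limma, 102 of them lower and 22 higher, and 2716 had an unadjusted p under 0.05. The median log2 change was -0.74 among the lower genes and 0.58 among the higher genes, and 27 genes changed by an absolute log2 of at least 1. Groups did not overlap for 4105 genes (24.3% of those tested, against 10% by chance). Counts changed when a single library was left out, which also leaves fewer samples. Leaving out wild-type library 2 left 52 called genes, and leaving out knockout library 1, 2 or 3 left 66, 57 or 58. Without wild-type library 3, which stands apart in ways given further on, 147 genes were called, 96 lower and 51 higher, so that the lower share moved from 82.3% to 65.3%, and 74 of the 102 lower genes were called lower again.

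The genes named for the largest decreases include secreted and matrix proteins. Ogn (chromosome 13, 49608046 to 49624501), which encodes the matrix proteoglycan osteoglycin, dropped from 29.6 ± 4.10 to 8.51 ± 0.990 FPKM (log2 -1.68, SE 0.12, adjusted p = 0.00138). Ntn1 (chromosome 11, 68209364 to 68400823), encoding the secreted guidance protein netrin-1, dropped from 10.2 ± 1.39 to 2.63 ± 0.288 FPKM (log2 -1.62), and Reln, encoding the secreted glycoprotein reelin, from 19.9 ± 2.13 to 5.81 ± 0.681 FPKM (log2 -1.61). Lox, whose product cross-links collagen and elastin, fell to 30.8% of wild type (log2 -1.53). The aldehyde oxidase Aox3 fell from 2.99 ± 0.286 to 0.297 ± 0.0796 FPKM, 9.91% of wild type (log2 -1.62). Clca3a1 (24.6% of wild type, log2 -1.63) and Myl9, the regulatory light chain of smooth muscle myosin (32.8% of wild type, log2 -1.60, adjusted p = 0.0302), were lower as well. Adjusted p was 0.00138 for each of these genes but Myl9, whose call was lost without any 1 library but knockout library 1 (adjusted p between 0.0554 and 0.139, the lowest without wild-type library 3).

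Fewer genes were called higher. Cck, which encodes the peptide cholecystokinin, rose from 1.72 ± 0.599 to 5.39 ± 0.949 FPKM (SD, n = 3 each; log2 1.25, adjusted p = 0.0326). Notum, a secreted enzyme that inactivates Wnt proteins, rose from 2.82 ± 0.602 to 7.62 ± 0.667 FPKM (log2 1.18, adjusted p = 0.00824). Cygb (cytoglobin, log2 0.90), Rergl (a Ras-like protein, log2 0.87), Col25a1 (a transmembrane collagen, log2 0.78) and Slc26a7 (an anion transporter, log2 0.74) rose to between 174% and 208% of wild type. Except for Col25a1, these calls depended on single libraries. Without wild-type library 2 or knockout library 1, Notum (adjusted p = 0.0563 and 0.0542) and Cygb (0.069 and 0.0568) were lost, and Cygb also without knockout library 2 (0.0676). Cck was lost without wild-type library 2 or any 1 knockout library (adjusted p between 0.0963 and 0.139), and Rergl and Slc26a7 without any 1 library but wild-type library 3 (0.0669 to 0.169 and 0.088 to 0.158). The rule also takes in the microRNA gene models Mir7022 and Mir7025. Both are listed at 0 in all 3 wild-type libraries and lie between 3.47 and 14.9 FPKM in knockout libraries, on models of 61 and 74 bp, where the 4.92 FPKM of Mir7025 in knockout library 2 correspond to about 1 fragment. Mir7025 lost its call without any 1 library but knockout library 2 (adjusted p between 0.0599 and 0.176). Clca3a1, Reln, Lox, Notum, Cygb, Tagln, Akr1b7 and Fn1 overlap exons of a gene on the opposite strand, which unstranded quantification would not separate, and Gucy1a1, Col3a1 and Mir7025 overlap a gene model on their own strand.

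**Figure D1:**
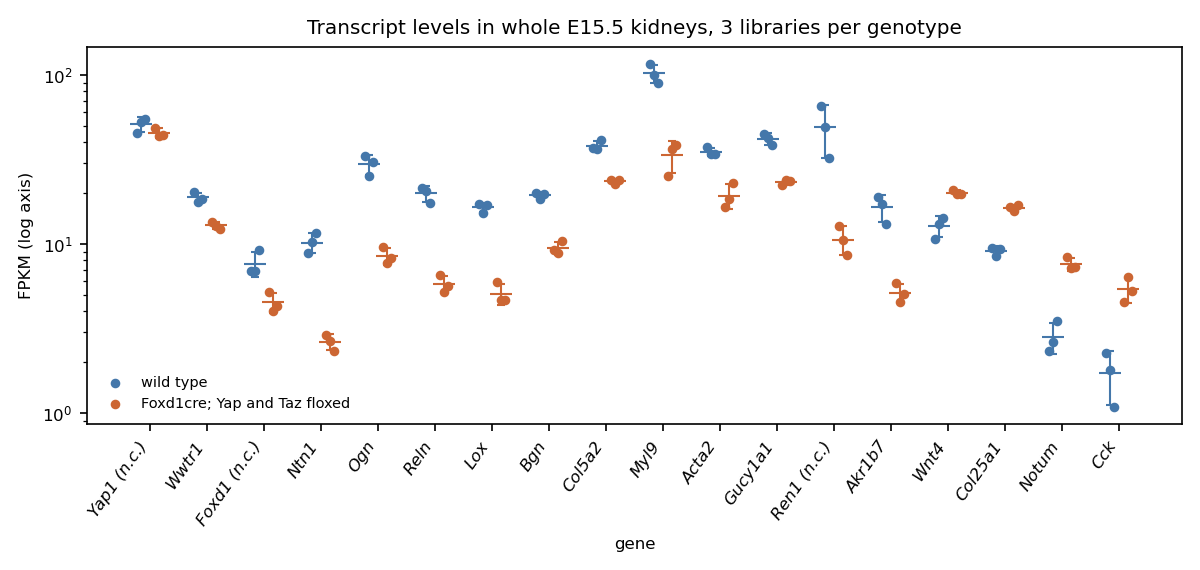
FPKM on a log axis for named genes in each library, wild type in blue and knockout in orange, with 3 points, the mean and the SD per genotype; "n.c." marks genes that were not called. Wwtr1 lies at 18.8 against 12.9 FPKM on average, Ntn1 at 10.2 against 2.63, and Yap1 at 51.0 against 45.4.

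In the smooth muscle list all 10 tested members lay below 0 and 3 were called lower, 4 when adjusted over the list alone. Acta2 (smooth muscle actin) fell from 35.2 ± 1.97 to 19.3 ± 3.22 FPKM (SD, n = 3 each; log2 -0.84, adjusted p = 0.023), Tagln (the actin-binding transgelin) had a log2 change of -0.86 (adjusted p = 0.0402), and Myl9 is given above. The list was called lower by camera (adjusted p = 4.47e-05) and fry (adjusted p = 0.0309) but not with an estimated correlation (adjusted p = 0.56). Wild-type library 3 lay above every other library for 6 of its 11 genes, and without it the camera adjusted p was 0.00474. Acta2 lost its call without any 1 library but knockout library 3 (adjusted p between 0.0543 and 0.126), and Tagln without any 1 library (0.0603 to 0.15).

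Of 20 tested genes of extracellular matrix proteins, 5 were called lower and 0 higher, against 10 lower and 1 higher when adjusted over the list alone. Bgn (biglycan) fell from 19.4 ± 0.784 to 9.46 ± 0.866 FPKM (log2 -0.97, adjusted p = 0.00263). The fibrillar collagen genes Col5a2 (log2 -0.67) and Col3a1 (log2 -0.62) and the fibronectin gene Fn1 (log2 -0.48) fell to 61.8%, 64.8% and 71.2% of wild type. The remaining called member, Fbn1 (fibrillin-1), named after its value was seen, had a log2 change of -0.48. Camera called the list lower (adjusted p = 0.00114), but fry did not (adjusted p = 0.176), nor did camera with an estimated correlation (adjusted p = 0.701). Wild-type library 3 lay above every other library for 13 of the 20 genes, with Col3a1 at 308 against at most 262 FPKM, and without it the camera adjusted p was 0.0415. Of its 20 members, 6 lay above 0, so the list did not move in 1 direction throughout. Col3a1 lost its call without wild-type library 2 or any 1 knockout library (adjusted p between 0.0651 and 0.118), and Fn1 without any 1 library but wild-type library 1 (0.0657 to 0.159).

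Stromal and perivascular lists were mixed. Among 13 cortical stroma genes Ntn1 was called over all genes tested, and 7 were lower and 0 higher when adjusted over the list alone. Foxd1, with the limit given for its allele, is a member. The list was called lower by camera (adjusted p = 0.0093) and by fry (adjusted p = 0.0309), and not with an estimated correlation (adjusted p = 0.56). Of 8 medullary stroma genes 0 were called by limma, 1 was higher and 2 were lower at an unadjusted p under 0.05, and 2 were lower when adjusted over the list alone. Penk, the proenkephalin gene (63.2 ± 11.1 against 39.2 ± 2.99 FPKM, log2 -0.66), and Tnc, the tenascin C gene (log2 -0.43), had an adjusted p of 0.0826 each, and the list was not called (adjusted p = 0.432). Penk was called without wild-type library 1 (adjusted p = 0.0497). Among 15 pericyte and mural genes Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, fell from 41.8 ± 3.39 to 23.2 ± 0.847 FPKM (SD, n = 3 each; log2 -0.82, adjusted p = 0.00359). Rgs5, a widely used pericyte marker, had a log2 change of -0.40 (adjusted p = 0.0723). When adjusted over the list alone 5 pericyte genes were lower and 2 higher, and the list was not called (adjusted p = 0.314). Wild-type library 3 lay above every other library for 9 of the 17 pericyte genes.

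Among 10 renin and mesangial genes Akr1b7, an aldo-keto reductase of renin cells, fell from 16.4 ± 3.01 to 5.15 ± 0.653 FPKM (log2 -1.49, SE 0.14, adjusted p = 0.0048). Ren1 itself, the renin gene, measured 49.1 ± 16.8 FPKM in wild-type and 10.6 ± 2.07 FPKM in knockout kidneys (SD, n = 3 each). With a 95% confidence interval of its log2 change from -2.86 to -1.27, it was not called (adjusted p = 0.0886), except without wild-type library 3 (adjusted p = 0.0218) or without robust moderation (0.0367). When adjusted over the list alone 4 members were lower and 2 higher. The list's median (0.07) lay above 0 while its mean (-0.30) and the camera direction lay below, and it was not called (adjusted p = 0.478).

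Of 20 tested genes known as targets of YAP and TAZ with TEAD factors in other cells, 0 were called by limma over all genes tested and 10 had an unadjusted p under 0.05, 8 lower and 2 higher. When adjusted over the list alone 7 were lower and 2 higher. Rbms3 had a log2 change of -0.27 (adjusted p = 0.0929) and Igfbp3 of -0.38 (adjusted p = 0.104). The list was not called (camera adjusted p = 0.179), except when knockout library 1 was left out (adjusted p = 0.0265, lower). Among 20 Hippo pathway components Wwtr1 was called, 2 were lower and 1 higher when adjusted over the list alone, and the list was not called (adjusted p = 0.253). Vgll4, a TEAD co-repressor, had a log2 change of 0.25 (adjusted p = 0.106).

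Members of the early nephron, nephron progenitor and ureteric tip lists lay mostly above 0. Among 10 early nephron genes Wnt4, a signal of the forming renal vesicle, rose from 12.7 ± 1.81 to 20.1 ± 0.737 FPKM (SD, n = 3 each; log2 0.63, adjusted p = 0.0402), and 5 members were higher when adjusted over the list alone. Bmper, a modulator of BMP signalling, had a log2 change of 0.36 (adjusted p = 0.0889). Wnt4 lost its call without wild-type library 2 or any 1 knockout library (adjusted p between 0.139 and 0.166). Of 15 nephron progenitor genes 14 lay above 0 (13 with quantile normalization), 0 were called by limma, 5 were higher at an unadjusted p under 0.05, and 2 were higher when adjusted over the list alone. Itga8, an integrin subunit that is also in the renin and mesangial list, had a log2 change of 0.41 (adjusted p = 0.117, and 0.0167 without wild-type library 1) and Hoxa11 of 0.26 (adjusted p = 0.131). All 9 ureteric tip genes lay above 0 (8 when rescaled to equal sums), 0 were called by limma, and 4 were higher at an unadjusted p under 0.05 and when adjusted over the list alone. The transcription factor gene Etv5 had a log2 change of 0.32 (adjusted p = 0.154). Camera called the early nephron (adjusted p = 0.00147), ureteric tip (adjusted p = 0.00219) and nephron progenitor lists (adjusted p = 0.00315) higher. With an estimated correlation their adjusted p was 0.562, 0.56 and 0.56. The nephron progenitor list was also called by fry (adjusted p = 0.0309).

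Among 11 collecting duct and urothelium genes 0 were called by limma, 6 were higher and 1 lower at an unadjusted p under 0.05, and 5 were higher and 1 lower when adjusted over the list alone. Calb1 (log2 0.22, adjusted p = 0.101) and Hoxb7 (log2 0.25, adjusted p = 0.144) had the smallest p. Camera called the list higher (adjusted p = 0.033, and adjusted p = 0.701 with an estimated correlation), but not with no filter on low values (adjusted p = 0.0571) or without wild-type library 3 (adjusted p = 0.415), in which 8 of its 12 genes lay below every other library. Of 9 immediate early and heat shock genes, which respond to dissection, 0 were called by limma, 3 were higher at an unadjusted p under 0.05, and 2 were higher when adjusted over the list alone. Jun had a log2 change of 0.65 (adjusted p = 0.0894, and 0.0257 without wild-type library 3) and Ier2 of 0.49 (adjusted p = 0.118). The list was called higher by camera (adjusted p = 0.0357), not with an estimated correlation (adjusted p = 0.701) and not without wild-type library 1, wild-type library 2 or knockout library 1 (adjusted p = 0.184, 0.0546 and 0.13) or with no filter on low values (adjusted p = 0.062).

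**Figure D2:**
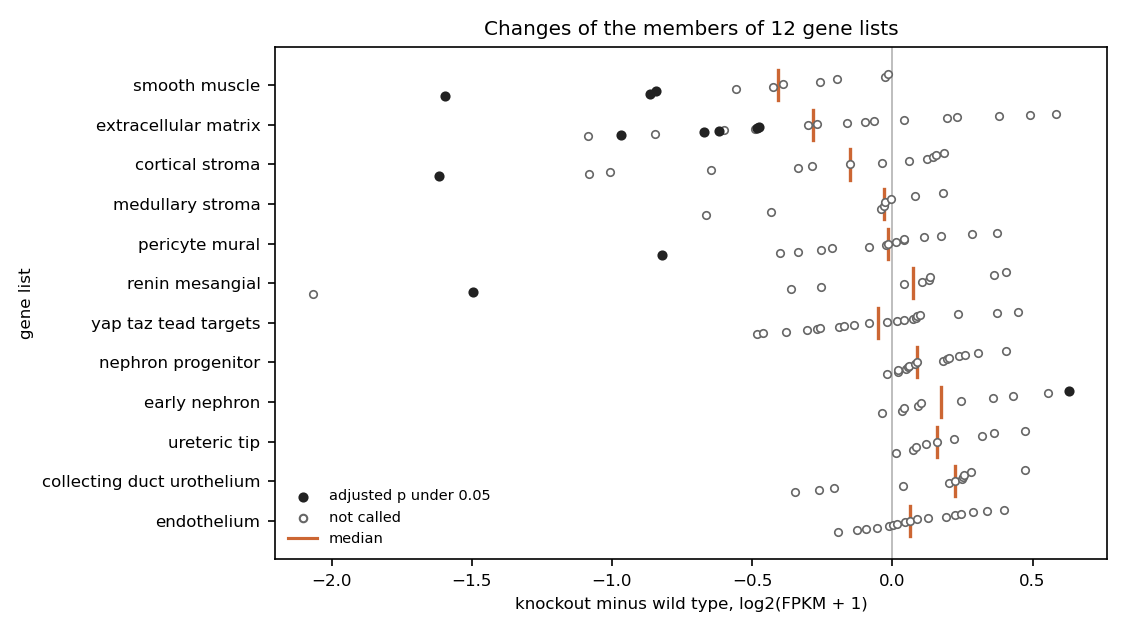
Log2 change, knockout minus wild type, of each tested member of 12 gene lists, with filled points for genes called at an adjusted p under 0.05, open points for the others and an orange bar at each list's median. All 10 smooth muscle genes lie below 0 and all 9 ureteric tip genes above 0 (8 when rescaled to equal sums), while pericyte and renin lists spread to both sides.

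The remaining lists were not called by camera, and with an estimated correlation 0 of the 31 lists tested were called. Among 12 podocyte genes Wt1 (log2 0.30) and Thsd7a (log2 -0.38) had the smallest p, 0 were called by limma, 2 were higher and 3 lower at an unadjusted p under 0.05, and 1 was higher and 2 lower when adjusted over the list alone (list adjusted p = 0.971). Its median of 0.02 and the camera direction lay above 0, its mean of -0.02 and the fry direction below. Of 17 endothelial genes 12 lay above 0 (10 when rescaled to equal sums) and 0 were called either way, with 5 higher and 1 lower at an unadjusted p under 0.05 and log2 changes of 0.40 for Plvap and 0.34 for Robo4 (list adjusted p = 0.179). Calls were also 0 either way for 13 macrophage genes, with 0 at an unadjusted p under 0.05 (Ptprc log2 -0.20, Csf1r -0.19, list adjusted p = 0.253, and 0.0443, lower, without wild-type library 2). Of 10 loop and distal tubule genes 0 were called either way and 2 were higher and 1 lower unadjusted (Pou3f3 0.16, Irx1 0.31, list adjusted p = 0.988), and their median (-0.04) and mean (-0.06) lay below 0 while the camera direction lay above. Hypoxia (11 genes, 1 higher unadjusted, Vegfa 0.20, Ankrd37 -0.18, list adjusted p = 0.415) and interferon genes (9 genes, 0 unadjusted, Ifi44 -0.14, Ifit1 0.21, list adjusted p = 0.971) had 0 calls either way. Of 15 cell cycle genes 0 were called, 2 were higher unadjusted and 1 was higher when adjusted over the list alone (Plk1 0.32, Aurkb 0.28, list adjusted p = 0.432, and 0.0265, higher, without knockout library 1). Of 11 p53 target and injury genes 0 were called either way and 4 were higher and 1 lower unadjusted (Cdkn1a 0.35, Bax 0.23, list adjusted p = 0.397). Its mean of 0.11 lay above 0 and its median of -0.02 below, and fry called it higher (adjusted p = 0.0309). Markers of red blood cells (Slc4a1 0.20, list adjusted p = 0.639), mitochondrial transcripts (mt-Co1 -0.06, mt-Atp6 0.04, adjusted p = 0.971) and liver (Fgb 0.40, Serpina1a 0.22, adjusted p = 0.397) had 0 calls either way, and unadjusted 1 liver gene was higher. The median of the mitochondrial transcripts lay just above 0, and their mean and the camera direction below. Cartilage genes had 0 calls over all genes tested, and 2 higher and 1 lower both unadjusted and when adjusted over the list alone (Col9a1 0.56, Col2a1 0.55, list adjusted p = 0.253). Only 1 gonad gene passed the filter (Pou5f1, log2 0.09), so that list was not tested.

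Wild-type library 3 differed from the other 5 libraries in sex-linked, nerve and muscle transcripts. Its Xist level was 121 FPKM, against at most 0.155 FPKM elsewhere, and its Ddx3y level was 0.353 FPKM, while both other wild-type libraries and all knockout libraries carried the Y-linked genes. The sex-linked list was not called between genotypes (Xist log2 -2.27, Eif2s3y 1.70, list adjusted p = 0.502), but was called lower without this library (adjusted p = 0.0464). Th, a marker of sympathetic neurons and chromaffin cells, measured 17.8 FPKM in this library and at most 0.0918 FPKM in any other, and Chgb measured 27.4 against at most 0.227 FPKM. All 8 skeletal muscle genes were at least 2 times as high in it as in any other library, with Myh3 at 29.1 against at most 4.98 FPKM. Xist, Ddx3y, Th, Chgb and Myh3 are control genes singled out after their values were seen. Between genotypes the nerve and chromaffin list (Stmn2 log2 -1.21, Prph -1.19, list adjusted p = 0.154, and 0.0209 and 0.0157, lower, without wild-type library 1 or 2), the skeletal muscle list (Tnnc2 -1.03, Myh3 -0.93, adjusted p = 0.413, and 0.0433, lower, without wild-type library 1), the adrenal cortex list (Mc2r 0.32, Fdx1 -0.14, adjusted p = 0.971) and the glia list (Erbb3 0.34, Fabp7 -0.57, adjusted p = 0.971) were not called with all libraries. Erbb3 was higher unadjusted and when adjusted over the list alone. The sex-linked, nerve, muscle and adrenal lists had 0 members past either adjustment and, unadjusted, 1 adrenal gene was higher.

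Proximal tubule genes were lowest in the same library, where 15 of 16 lay below every other library. With all libraries the list of 14 tested genes was not called (Hnf4a log2 0.35, Cubn -0.27, list adjusted p = 0.801), 0 members passed either adjustment and 1 was higher unadjusted. Without wild-type library 3 it was called lower in knockout kidneys (adjusted p = 0.00175).

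**Figure D3:**
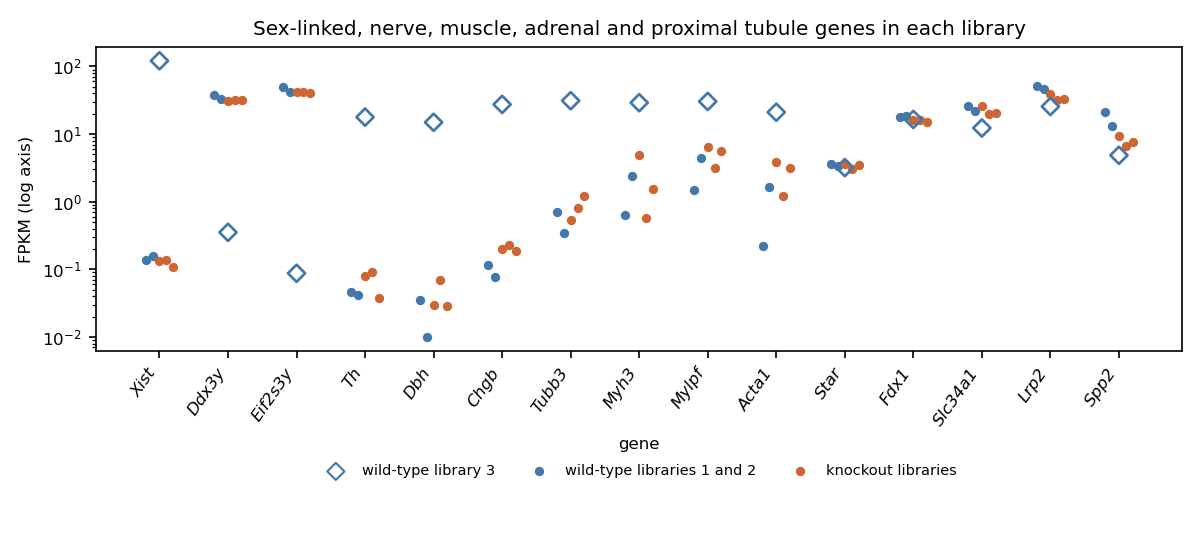
FPKM on a log axis of sex-linked, nerve, muscle, adrenal cortex and proximal tubule genes in each library, with wild-type library 3 as open diamonds, the other wild-type libraries in blue and the knockout libraries in orange; values under 0.01 are drawn at 0.01. Xist (121 FPKM), Th (17.8 FPKM) and Myh3 (29.1 FPKM) stand far above the other 5 libraries in wild-type library 3, and Star does not.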

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

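All 124 calls kept their direction in every other fit in which the gene was tested. The genotypes did not overlap for any of these 124 genes, so leaving out a library could not have reversed a direction. Only the short RNA alternative was added after the data had been seen. The number called, 124 with all libraries, ranged from 52 to 147 when 1 library was left out (higher 7 to 51, lower 45 to 96). Genes with a mean of at least 5 FPKM gave 44 higher genes, and leaving out short RNA models gave 205 calls, 55 of them higher, from fewer genes tested, and the cause was not tested further. Equal sums per library gave 12 higher genes, and 13 without globin and mitochondrial genes, for which the cause was not tested. Size factors moved nothing, since the values already carried them, and the alternative for count tables was not run, because the values are FPKM. An adjusted p under 0.01 left 43 genes (4 higher, 39 lower), and an absolute log2 of at least 1 left 27 (4 higher, 23 lower). Except for the replicate block, given further on, the other settings stayed within 1.5 times of the counts reported.

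Wwtr1 ranged from -0.55 to -0.46 on the log2 scale with a library left out. It lost its call with equal sums (-0.53, adjusted p = 0.0516), and without globin and mitochondrial genes (-0.53, adjusted p = 0.0526), and the cause was not tested. Of the 26 named genes that were called, 13 to 21 were called with a library left out, where fewer samples enter. Akr1b7, Aox3, Bgn, Clca3a1, Col25a1, Col5a2, Gucy1a1, Lox, Ntn1, Ogn and Reln were among those called in all other fits in which they were tested, while Tagln lost its call in 10 of 16. Of 31 lists, 8 were called, 8 or 9 with a library left out, 0 with an estimated correlation and 4 by fry. With no filter on low values 6 were called, without the collecting duct (adjusted p = 0.0571) and immediate early lists (0.062), and with a mean of at least 5 FPKM 7 were called, the immediate early list then having too few genes to be tested. The sex-linked list turned lower without wild-type library 3 (adjusted p = 0.0464, and up to 0.612 without another library), which carries the female pattern.

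The labels number libraries 1 to 3 in each genotype. Deviations of same-numbered libraries correlated at 0.02, -0.04 and 0.05. Wild-type libraries 1 and 3 matched the knockout library of their own number best, and wild-type library 2 matched knockout library 1. With correlations this near 0 the numbers were not taken to pair samples. With a replicate block 32 genes were called (2 higher, 30 lower), 13 of the named genes, and Wwtr1 was not (log2 -0.51, adjusted p = 0.108), with fewer residual degrees of freedom.

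The depth of 12700000 to 15500000 fragments limits low genes most. On a model of 61 bp 1 fragment was worth 3.51 to 4.57 FPKM in knockout libraries, far above the filter of 0.5 FPKM.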

Other observations

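Genes in this part were chosen after their values were seen, unless a list or rule above names them. The tests of splits were written before the results were known, and all other tests in this part were chosen after the result was seen.

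Several further secreted proteins and matrix components outside the fixed lists were called lower. They were picked from the called genes, and whether such genes are over-represented among them was not tested. Col12a1, a collagen of fibril surfaces, fell from 24.0 ± 0.778 to 8.47 ± 1.21 FPKM (SD, n = 3 each; log2 -1.41), and Thbs2, encoding the matricellular protein thrombospondin-2, from 12.7 ± 1.18 to 4.27 ± 0.0981 FPKM (log2 -1.38). Col14a1 (log2 -0.63), the laminin chain gene Lama2 (log2 -0.94) and the basement membrane gene Nid1 (log2 -0.49) were also lower. Growth factors in this set were Hgf (log2 -0.79), Vegfd (log2 -0.85), Angpt2 (log2 -0.52) and Ptn (log2 -0.55). The guidance gene Sema3a (log2 -0.65) and the adhesion gene Alcam, which fell from 89.6 ± 4.56 to 41.1 ± 0.996 FPKM (log2 -1.10), moved the same way as Ntn1 and Reln. Gucy1a2, a further subunit of the nitric oxide receptor, fell with Gucy1a1 (log2 -0.57), and the third subunit gene, Gucy1b1, had a log2 change of -0.34 that was not called (adjusted p = 0.178). Gucy1a2 (chromosome 9, 3532778 to 3894736) lies within 10 Mb of the floxed gene Yap1, so its fall may reflect DNA linked to that locus, which was not tested. The complement regulator Serping1 (log2 -0.99) and the cytokine gene Il33 (log2 -1.26) were lower. The Wnt inhibitor gene Sfrp1 was lower (log2 -0.86), while Notum and Wnt4 were higher, and Wnt pathway genes were not tested as a set.

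Some of the genes called lower are imprinted. Peg3 fell from 115 ± 5.04 to 79.6 ± 2.37 FPKM (log2 -0.53), and Mest from 441 ± 20.8 to 333 ± 5.80 FPKM (log2 -0.40). Zim1 (log2 -1.01), Plagl1 (log2 -0.68) and Slc38a4 (log2 -0.35) were called lower as well. In a list of 43 imprinted genes drawn up after some of these had been noticed, 5 of 37 tested members were called lower, against 0.223 expected (one-sided Fisher's exact test, p = 2.71e-06, odds ratio 27.0). Because the list followed the observation and includes the genes that prompted it, this test cannot decide whether imprinted genes are over-represented among the lower genes. Igf2, at 162 ± 7.89 and 146 ± 5.66 FPKM, was not called (log2 -0.15, adjusted p = 0.276).

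A lower share of all stromal cells alike, as a source of the fall of 102 genes, would lower the fixed stroma genes by about the same amount. Of 21 cortical and medullary stroma genes, 16 had 95% intervals wholly above the median of the lower genes (-0.74), among them Pdgfra (0.14, interval -0.01 to 0.30), which argues against an even loss. Wild-type library 3 as the whole cause is argued against by the 74 genes called lower without it, with a median of -0.75 for the 102 genes in that fit. DNA of another strain around Yap1, Wwtr1 and Foxd1 was examined within 10 Mb of them. Beside these genes, 3 lower genes lay there (Gucy1a2 near Yap1, Pcdh18 and Ptx3 near Wwtr1), against 1.53 expected from 253 tested. This argues against DNA in that window as a direct source for the other lower genes. The window was chosen after the result was seen. Longer segments, effects on distant genes and differences elsewhere in the mixed strain were not tested and stay open. The genotype itself, a loss of some stromal cell types, and differences between litters or embryos stay open, as untested.

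The 6 libraries can be split into 10 pairs of equal groups, which is too few for a share under 0.05. The real split gave 124 genes and the highest other 19, so that 1 split gave as many. For gene lists the real split gave 8 and the highest other, which set wild-type library 1 with knockout libraries 1 and 2, also gave 8, so that 2 splits gave as many.

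Nerve and muscle transcripts of wild-type library 3 may come from tissue next to the kidney. All 8 skeletal muscle genes fixed in advance were at least 2 times as high as in any other library, as were 8 of 9 nerve and chromaffin genes. Mylpf measured 30.3 against at most 6.46 FPKM, and Actc1 21.8 against at most 4.55 FPKM. These counts restate the pattern, so they cannot decide its source, and muscle and ganglion from outside the kidney stay open. For adrenal gland the result was divided, since 3 of 9 adrenal cortex genes met the same mark. These were Hsd3b1 (1.22 against at most 0.162 FPKM) and, at low values, Cyp21a1 (0.319 against 0.0837 FPKM) and Cyp11b1 (0.156 against 0.0295 FPKM). Star (3.19 against 3.66 FPKM) and Fdx1 (16.5 against 18.3 FPKM), which the kidney libraries also express, did not. Neither did Mc2r (1.54 against 2.01 FPKM), Cyp11a1 (0.653 against 0.545 FPKM), Nr5a1 (0.201 against 0.131 FPKM) or Cyp17a1 (0.0418 against 0.158 FPKM). Adrenal tissue therefore stays open. No biological explanation was tested, and the sex of the embryo, which differs in this library alone, stays open.

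The microRNA models Mir7022 and Mir7025 may reflect a few fragments on a very short gene model. From the step of 1 fragment on models of like length, their knockout values equal 1 to 4 fragments per library, with 4 the highest (Mir7025, knockout library 3). Mir7022 (chromosome 4, 148146936 to 148146996, GRCm38) lies within Fbxo6 and Mir7025 (chromosome 5, 75176831 to 75176904) overlaps an exon of Pdgfra, on the same strand. All 9 short RNA models called lie within the span of another gene. A difference between genotypes in the microRNAs themselves stays open, as untested.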
